A study of Scylla paramamosain with 3 samples.

How the data were processed

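Messenger RNA of hemocytes was sequenced on an Illumina HiSeq instrument from TruSeq RNA libraries made with 1 µg of Trizol-extracted total RNA, per the labels' protocols. The design text of the labels speaks of triplicates, while the table used here has 1 column of counts for the uninjected 0 h condition and 1 for the 24 h condition, so that n is 1 library per group. How many crabs went into each library is not given in the sources used here. The libraries were assigned to groups by their titles and source names, and the table's columns by the same titles. Crabs injected with saline, which the labels mention, are not analysed here, so that the effects of injection, of time and of the bacterium are not separated.

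The deposited table lists 73375 unigenes of an assembled transcriptome, from 200 to 13911 bases long with a median of 343. Per the file headers it gives for each unigene the read count, the RPKM (reads scaled to unigene length and to the total of counted reads), the authors' log2 ratio, and a p-value with an FDR. Counts are whole numbers as the authors deposited them. The deposited RPKM values were recomputed from counts, lengths and column sums to within a relative deviation of 1e-09, so that the column sums are the totals the authors used. A count of 0 is written as an RPKM of 0.001 in the deposited table, and the authors' log2 ratio takes that value as it stands. The test behind the authors' deposited p-value, the read mapper and the assembler are not given in the sources used here. Best protein matches were given for 19260 unigenes and Gene Ontology processes for 6050, per the file headers. No genome was used, so no coordinates are given and unigenes are identified by the table's own names. Unigenes of 1 cluster are similar sequences, and reads can be split between them. A match names the closest protein in a database and not a verified ortholog.

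The total count was 4837843 at 0 h and 4909167 at 24 h, 1.47% more, and 68714 and 67691 unigenes had at least 1 count. Ratios are ratios of CPM, counts scaled to library totals. Each has an exact 95% interval (Clopper-Pearson, from the binomial share of the 24 h library in the summed count). Reads were counted without molecular identifiers, so intervals cover counting error only and not the variation between crabs, bleedings or library preparations. A count of 0 allows up to 3 counts, which is 0.62 CPM at 0 h and 0.611 at 24 h, and folds against 0 were computed against those 3 counts per library. Such a fold takes the other library's count as exact, so that the bound of the exact interval, printed beside it, is lower. No test and no p-value across genes was computed, because there is 1 library per group. The size rule counts a unigene as higher or lower with a summed count of at least 20, a ratio of at least 2 or at most 0.5, and an interval that excludes 1. It was checked on simulated counts of 73375 unigenes drawn from these libraries with counting error only: 96.2% of intervals held the true ratio, 1.57% of 27703 unchanged unigenes passed, and of 50 unigenes changed at each size 40% passed at 2-fold and 100% at 4-fold, 8-fold and 16-fold.

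The rules, gene lists and first alternatives were fixed before the data were examined. There were 25 lists, defined by words in the protein names: antimicrobial peptides, prophenoloxidase system, pattern recognition receptors and lectins, protease inhibitors, Toll, IMD and NF-kB pathway, JAK-STAT pathway, MAP kinase pathway, RNA interference, clotting proteins, hematopoiesis factors, antioxidant enzymes, heat shock proteins and chaperones, apoptosis regulators, lysosomal proteins, cytosolic ribosomal proteins, nuclear-encoded respiratory chain, mitochondrially encoded transcripts, glycolysis, cell cycle and DNA replication, cytoskeleton, mobile elements, and markers of muscle, hepatopancreas, cuticle and nervous system. Some search words caught unrelated proteins, and a second version without those members was added after seeing the data. Where the Results do not give its size, it kept 26 of 28 lysosomal, 38 of 44 respiratory chain and 68 of 69 ribosomal unigenes. It also kept 61 of 71 cytoskeleton, 2 of 3 clotting and 3 of 5 JAK-STAT unigenes. Each list's median log2 ratio (0.5 added to each count) was placed among 10000 random lists of the same size drawn from unigenes with a protein match in 20 bins of mean expression. That percentile describes these 2 libraries and is not a test of the conditions. The interval of a median comes from binomial order statistics over the members, which are not independent replicates.

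Named unigenes follow 3 rules: the 12 highest and 12 lowest by the interval bound nearest to 1 among unigenes with an informative protein name, 1 per name, the 2 with most counts and the 2 farthest from 1 in each list, and the 5 with most counts in each library. Other list members named in the text were chosen after their values were seen: the crustin, arasin-like and lysozyme unigenes, CL2290.Contig3, the pacifastin-related inhibitor, prophenoloxidase and its activating enzyme III, clip domain serine proteinase 2, the scavenger receptor that fell, IKKepsilon2, the MAP kinase kinase kinase, the second catalase, the glutathione peroxidase, the second heat shock protein 21, the Niemann-Pick unigenes, the aldolase, pyruvate kinase 2, the chymotrypsins, preamylase and titin. So were the 4 unigenes without an informative name given beside the rankings. The alternatives were TMM factors from edgeR, median of ratios size factors, totals without the 10 most abundant unigenes, the deposited RPKM ratio, other count minimums, a ratio of 4, no interval, a minimum length of 500 bases, counts summed per protein description and a larger added count of 5. Alternatives added after seeing the data were unigenes with or without a protein match, scaling to the median of matched unigenes, and the reduced lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with edgeR 4.0.16 in R 4.3.3 for the TMM factors alone.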

Results

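Hemocytes, the circulating immune cells of crustaceans, were taken from the mud crab Scylla paramamosain and their messenger RNA was sequenced. The crabs weighed about 100 g and had been kept for 7 days at 25 °C in seawater tanks. Of the 3 libraries of the series, 1 came from crabs that had received no injection (0 h) and 1 from crabs 24 h after an intramuscular injection of the marine bacterium Vibrio parahaemolyticus, which was given to 20 crabs. The remaining library was a pool of hemocytes from 0 to 24 h that the labels give as the transcriptome sample, and it enters no comparison here. Read counts were available for 73375 unigenes, which are assembled transcript sequences named by cluster (CL) or singleton (Unigene) number. All identifiers end in OhDZ_1, which is left out here and resembles the title of the 0 h library, and which reads the unigenes were assembled from is not given in the sources used here. The 0 h library held 4837843 counted reads and the 24 h library 4909167. A protein match was given for 19260 unigenes, and protein names below are those best matches. With 1 library per group no difference has a replicate check. The intervals given in parentheses are 95% intervals that cover counting error only, or, for medians and shares of unigenes, the spread over unigenes only.

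The 24 h library was compared with the 0 h library for immune genes and pathways of the hemocyte. Injection, time and the bacterium differed together between them, so a difference cannot be assigned to the infection. Among the abundant immune transcripts, alpha-2-macroglobulin, a broad protease inhibitor of hemolymph, rose 2.05-fold (2.04 to 2.07) and 2 clip domain serine proteinases, enzymes of the melanization cascade, rose 3.16-fold and 4.01-fold. Several anti-lipopolysaccharide factors, peptides that bind bacterial lipopolysaccharide, rose as well, but the most abundant of them did not. The antimicrobial peptide crustin and an arasin-like peptide fell, although both missed the size rule with TMM factors in place of library totals. Peroxinectin, a cell adhesion protein of crustacean hemocytes, fell 2.93-fold (2.87 to 3.01), and a mannose-binding protein, a name used for sugar-recognizing lectins, fell 5.42-fold (4.88 to 6.03). Heat shock protein 21, catalase, selenium-dependent glutathione peroxidase and metallothionein-1 rose, while cathepsins A and D, proteases of the lysosome, fell, although cathepsin A missed the size rule with TMM factors in place of library totals. A unigene is said to have risen or fallen only where its summed count was at least 20, its ratio of CPM (counts scaled to the library total) was at least 2 or at most 0.5, and the counting interval excluded 1. Of tested unigenes with a protein match 4.89% rose and 5.89% fell, so a few such members in a list below can be near these shares.

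Of 14 unigenes named as antimicrobial peptides or lysozymes, 5 rose, 3 fell and 6 did neither. Their counts summed to 72102 at 0 h and 74728 at 24 h, a ratio of 1.02 (1.01 to 1.03). Most counts over both libraries fell on anti-lipopolysaccharide factor 2 (Unigene1095), with 20566 counts at 0 h and 27788 at 24 h, a ratio of 1.33 (1.31 to 1.36). An anti-lipopolysaccharide factor of nearly the same abundance (CL2290.Contig2) had a ratio of 1.02. A second contig of that cluster (CL2290.Contig3) rose 2.02-fold (1.95 to 2.09), and contigs of 1 cluster can share reads. Rarer family members rose further, with anti-lipopolysaccharide factor isoform 6 (Unigene1551) going from 21 to 168 counts, 7.88-fold (4.99 to 13.1), and a further factor 2 unigene (Unigene1773) rising 3.78-fold (3.05 to 4.72). Crustin (Unigene1116), a cysteine-rich antibacterial peptide, fell 2.09-fold (2.04 to 2.14), and an arasin-like peptide (Unigene1092) fell 2.08-fold (1.94 to 2.23). With TMM factors in place of library totals both peptides missed the size rule, at ratios of 0.548 and 0.55. A lysozyme unigene (Unigene18267), an enzyme that cuts bacterial cell walls, fell from 25 to 4 counts.

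In the prophenoloxidase system, which leads to melanin deposition around microbes, 5 of 26 unigenes rose and 4 fell, or 7 and 2 with TMM factors. The 5 increases were all in clip domain serine proteinases, led by Unigene1147 with 6086 counts at 0 h and 19543 at 24 h (3.07 to 3.26) and by Unigene1284 with 1969 and 8004 counts (3.81 to 4.21). The decreases were peroxinectin (Unigene1252), with 26073 counts at 0 h and 9015 at 24 h, a masquerade-like serine proteinase homolog (Unigene1452) at 3.06-fold (2.81 to 3.32), prophenoloxidase activating enzyme III (CL365.Contig1) and clip domain serine proteinase 2 (CL2097.Contig4). The last 2 missed the rule with TMM factors, at ratios of 0.523 and 0.528. The unigene named prophenoloxidase itself (CL3845.Contig1), the enzyme precursor of the cascade, had 47 and 44 counts, a ratio of 0.923.

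**Figure D1:**
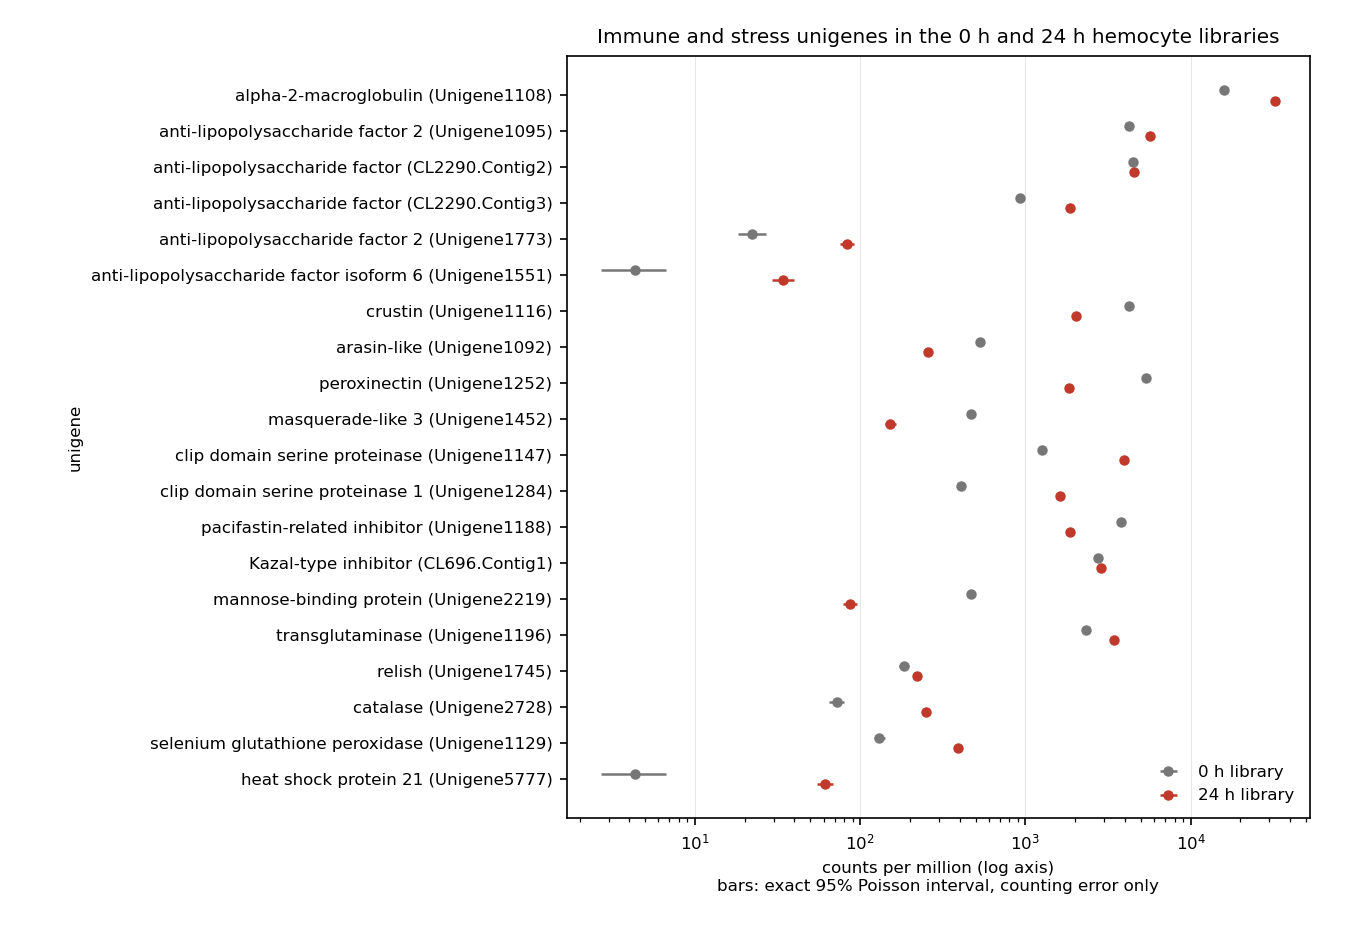
CPM of 20 immune and stress unigenes (rows) on a log axis in the 0 h library (grey) and the 24 h library (red), with exact 95% Poisson intervals that cover counting error only, the rows having been chosen for display after the values were seen. Alpha-2-macroglobulin lies farthest to the right in both libraries, at 15889 and 32623 CPM, and crustin, arasin-like, peroxinectin, masquerade-like, pacifastin-related and mannose-binding unigenes lie further left at 24 h, of which crustin, arasin-like and pacifastin-related miss the size rule with TMM factors.

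Among 23 protease inhibitors, 2 rose and 3 fell, whereas 3 rose and 1 fell with TMM factors. Alpha-2-macroglobulin (Unigene1108) took 1.59% of all counts at 0 h (exact binomial interval 1.58 to 1.60) and 3.26% at 24 h (3.25 to 3.28), the largest number of counts of any unigene in either library. A Kazal-type inhibitor (CL696.Contig1) had a ratio of 1.04 (1.02 to 1.07). A second Kazal-type unigene (Unigene1176), whose best match came from the male reproductive tract of a prawn, fell 2.63-fold (2.53 to 2.73). A pacifastin-related inhibitor (Unigene1188), of a family that blocks prophenoloxidase activation in crayfish, fell 2.02-fold with library totals and had a ratio of 0.565 with TMM factors, short of the rule.

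Of 24 unigenes in the list of pattern recognition receptors and lectins, which detect microbial surfaces, 3 rose and 2 fell, or 4 and 1 with TMM factors. The 18 left without proteins of other functions held the same 3 and 2. Hemolectin (Unigene2834) and a mannan-binding lectin serine protease (Unigene1215) were the most abundant, with ratios of 1.28 and 1.18. A C-type lectin (Unigene31175) was read 24 times at 24 h and 0 times at 0 h, at least 7.88-fold higher against the 3 counts that a count of 0 allows, with an exact interval bound of 5.93. A soluble scavenger receptor (Unigene27048) rose from 7 to 31 counts, and another (Unigene46667) fell from 31 to 9.

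The intracellular signalling lists held few changes. The shares over all unigenes tested were 4.55% higher and 8.87% lower, or 4.89% and 5.89% among those with a protein match. At these shares lists of this size would hold few as well. Of 37 unigenes in the Toll, IMD and NF-kB list, the main routes from microbial recognition to peptide genes, none rose and 3 fell, or 1 and 2 with TMM factors, and 14 of the 37 were intracellular trafficking or intraflagellar transport proteins caught by the search words. In the remaining 23, only the kinase IKKepsilon2 (Unigene8992) fell, from 28 to 11 counts. Relish (Unigene1745), the NF-kB factor of the IMD pathway, had 893 and 1085 counts (ratio interval 1.09 to 1.31), and a Toll-like receptor (CL4564.Contig1) a ratio of 0.606 (0.508 to 0.723). None of 19 unigenes in the MAP kinase list rose and 1, a kinase kinase kinase 4, fell by the rule but not with TMM factors. Of the 19, 15 were left without proteins of other functions, and none of these rose and 1 fell. Mitogen-activated protein kinase (Unigene2081) had a ratio of 0.794 (0.756 to 0.834). Of 5 JAK-STAT unigenes 1 fell, a SPRY domain SOCS box protein (Unigene3877) that acts outside that pathway, and the Janus kinase unigene (Unigene18227) had 115 and 71 counts. All 12 RNA interference unigenes stayed within the rule, among them argonaute 2 (Unigene6828) with 323 and 324 counts and dicer 2 (Unigene11) with 100 and 71.

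Of 3 clotting unigenes none passed, with transglutaminase (Unigene1196), which cross-links the clot, at a ratio of 1.49 (1.45 to 1.52) and the clotting protein precursor (Unigene11935) at 0.944. Among 4 hematopoiesis factors, the transcription factor named GATA binding protein 5 (CL4915.Contig2) rose 2.35-fold (1.75 to 3.19). Astakine 2 (Unigene1221), a cytokine of crustacean blood cell formation, had 1804 counts at 0 h and 2576 at 24 h, a ratio of 1.41.

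Among 32 antioxidant unigenes 4 rose and 1 fell, or 5 and 1 with TMM factors. The list's median log2 ratio was −0.23 (−0.38 to 0.12) with library totals and −0.04 with TMM factors. With library totals it was above only 3.26% of the random lists, though within their middle range of −0.25 to 0.15. The increases named here are therefore those of single unigenes and not of the list. Catalase, which breaks down hydrogen peroxide, rose in both of its unigenes with most counts, 3.45-fold (3.06 to 3.90) in Unigene2728 and 2.61-fold (2.23 to 3.05) in Unigene4098. Selenium-dependent glutathione peroxidase (Unigene1129) rose 2.98-fold (2.72 to 3.26), and metallothionein-1 (CL2652.Contig1), a metal-binding protein, went from 6 to 90 counts, 14.8-fold (6.53 to 41.3). Ferritin (Unigene1213), the iron store, and copper/zinc superoxide dismutase (Unigene1222) were the most abundant members, at ratios of 0.899 and 1.03.

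The 33 unigenes in the list of heat shock proteins and chaperones, which help proteins fold, had a median log2 ratio of 0.17, above 98.8% of 10000 random lists matched on expression. In the 26 left without proteins of other functions that median was 0.27, above 99.8% of such lists. Only heat shock protein 21 (Unigene5777) passed, from 21 to 300 counts, 14.1-fold (9.04 to 23.1), and another unigene of that name (CL1006.Contig1) had 22 and 18. Heat shock protein 90 (Unigene1411), protein disulfide isomerase (Unigene1313) and heat shock protein 70 (CL387.Contig2) had ratios of 1.93, 1.72 and 1.27. With TMM factors 6 members passed, heat shock protein 90 among them at 2.20.

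The 28 lysosomal unigenes had a median log2 ratio of −0.42, above only 0.18% of the random lists, with 3 members up and 3 down, or 4 and 1 with TMM factors. Cathepsin D (Unigene5790) fell 2.87-fold (2.35 to 3.52) and cathepsin A (Unigene1779) fell 2.20-fold (2.05 to 2.36), the latter at a ratio of 0.52 with TMM factors. Saposin (Unigene1665), a cofactor of lipid breakdown, and the proteolipid subunit of the vacuolar proton pump (Unigene1681) had ratios of 0.716 and 0.589. The increases included 2 unigenes of Niemann-Pick C1 protein, a cholesterol exporter of the lysosome, at 2.14-fold and 2.12-fold. Of 28 apoptosis regulators 2 rose and 3 fell, or 2 and 2 with TMM factors. A caspase (Unigene24309), a protease of programmed cell death, went from 32 to 3 counts, 10.8-fold lower (3.39 to 55.2), and an inhibitor of apoptosis protein (Unigene1757) had a ratio of 1.60. A BCL2-interacting protein unigene (Unigene24045) rose from 10 to 40 counts.

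None of 69 cytosolic ribosomal protein unigenes passed the rule, while their median log2 ratio of 0.16 exceeded 99.4% of the random lists, and ribosomal proteins L7 (Unigene1230) and L3 (Unigene1180) had ratios of 1.32 and 1.48. The 44 nuclear-encoded respiratory chain unigenes had a median of −0.30, above 0.23% of the random lists, with the ATP synthase alpha precursor (Unigene1577) at a ratio of 0.702 and 1 member lower by the rule, whose best match was to an amoeba. The 29 unigenes of mitochondrially encoded transcripts had a median of −0.33, above 1.11% of the lists, with 1 up and 3 down, or 1 and 2 with TMM factors, and the 4 that passed had best matches outside the crab. Only 7 of the 29 were matched to the crab, with a median of −0.39, above 2.12% of the lists, and none of them passed. Cytochrome c oxidase subunits I (Unigene1118) and III (Unigene1124) of the crab had ratios of 0.761 and 0.704. Crab mitochondrial transcripts took 3.13% of counts at 0 h and 2.31% at 24 h.

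Among 9 glycolysis unigenes, a low-count aldolase rose and pyruvate kinase 2 (CL1697.Contig2) fell, with 2 up and 1 down under TMM factors, and the abundant glyceraldehyde-3-phosphate dehydrogenase (CL5683.Contig1) had a ratio of 0.826. Of 44 cell cycle and DNA replication unigenes 1 rose and 4 fell, while 3 rose and 3 fell with TMM factors, and among the 40 left without proteins of other functions none rose. The fallen ones were 3 unigenes of minichromosome maintenance proteins, the replicative helicase, of which 1 missed the rule with TMM factors, and a kinetochore protein, led by MCM7 (Unigene25375) with 35 and 10 counts. Among 71 actin and tubulin cytoskeleton unigenes 5 rose and none fell, or 7 and 0 with TMM factors, 1 of the 5 being a metalloproteinase caught by the search words. Integrin alpha-PS4 (Unigene1869), a matrix receptor, rose 3.36-fold (3.21 to 3.51) and an actin capping protein (CL3133.Contig1) 3.78-fold (3.08 to 4.68). Beta-actin (CL1584.Contig2) had a ratio of 1.82 (1.81 to 1.84) with library totals and passed with TMM factors, at 2.08. The list's median was −0.09 and turned to 0.10 with TMM factors.

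Markers of other tissues were measured beside these groups. Hepatopancreas markers, of the digestive gland, had a median log2 ratio of 0.42 over 19 unigenes, above 99.9% of the random lists, with 4 up and 2 down, or 4 and 0 with TMM factors. The search words also caught 11 proteins of other functions, and the 8 left had a median of 1.98 (−1.12 to 7.75), with 4 up and 1 down. The 4 increases were cryptocyanin (CL79.Contig1), a hemocyanin-related protein of moulting crabs that was read 109 times at 24 h and 0 times at 0 h, a trypsin-like proteinase (CL2174.Contig1) and 2 contigs of chymotrypsin. The trypsin-like unigene had 1 and 48 counts (ratio 47.3, 8.09 to 1907) and the main chymotrypsin contig (CL1852.Contig2) 4 and 53 (ratio 13.1, 4.81 to 49.7). Preamylase (Unigene28929) went from 22 to 10, which did not pass with TMM factors. None of 30 muscle marker unigenes rose and 3 fell, or 2 with TMM factors, with arginine kinase (Unigene1160) and tropomyosin (Unigene1134) at ratios of 1.18 and 1.40 and titin (Unigene15605) at 36 and 15 counts. Of 3 cuticle unigenes an arthrodial cuticle protein (Unigene12078) rose from 5 to 30 counts. None of 5 unigenes in the nervous system list passed, with synaptotagmin (Unigene9114) at 211 and 198 counts, and 2 of the 5 were left without proteins of other functions.

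**Figure D2:**
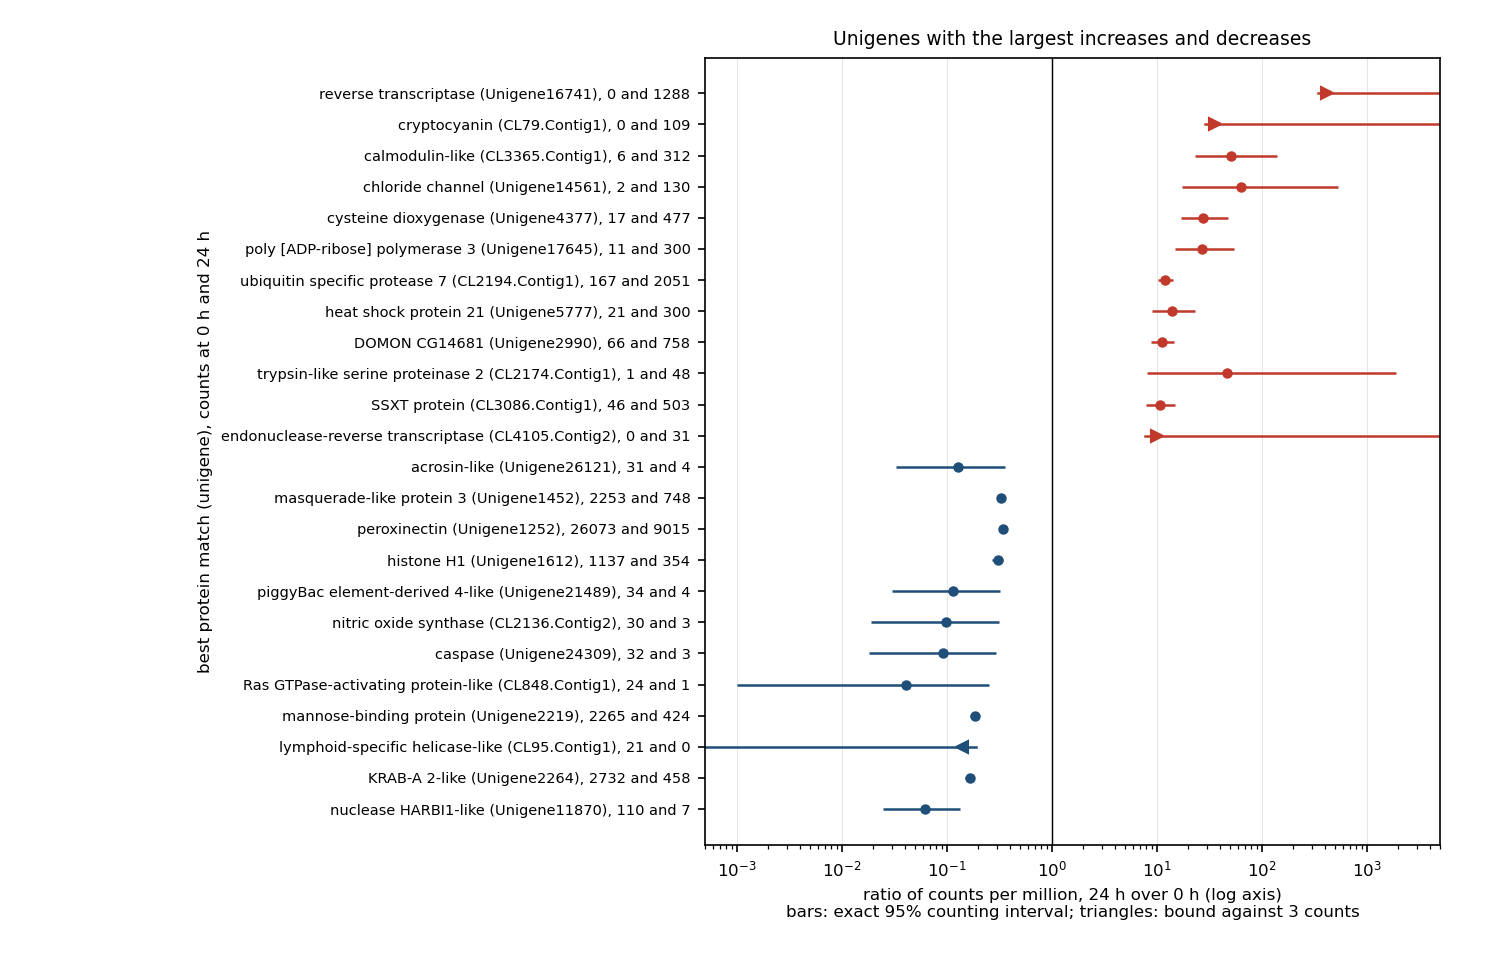
Ratios of CPM (24 h over 0 h, log axis) of the 12 unigenes with the largest increases (red) and the 12 with the largest decreases (blue) by the naming rule, each with its counts and its exact 95% counting interval, triangles marking bounds against the 3 counts that a count of 0 allows. Against those 3 counts the increases run from at least 423-fold for a reverse transcriptase (exact interval bound 344) down to at least 10.2-fold for an endonuclease-reverse transcriptase (bound 7.80), and peroxinectin has the narrowest interval among the decreases, at 2.87 to 3.01.

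Among unigenes with an informative protein name, ranked by the interval bound nearest to 1, the largest increase was in a unigene weakly matched to a reverse transcriptase (Unigene16741), with 1288 counts at 24 h and 0 at 0 h, at least 423-fold against 3 counts, with an exact interval bound of 344. Cryptocyanin was next in that ranking, at least 35.8-fold higher against 3 counts, with a bound of 28.6. Outside it, a unigene matched to an unnamed protein (CL763.Contig1) had 1 and 1427 counts, a ratio of 1406 (252 to 55583), and 2 unigenes without a match (Unigene13322 and Unigene17149) had 161 and 116 counts at 24 h and 0 at 0 h. A calmodulin-like calcium sensor (CL3365.Contig1) rose from 6 to 312 counts, 51.2-fold (23.3 to 141). Cysteine dioxygenase (Unigene4377), which degrades cysteine, rose 27.7-fold (17.1 to 47.9), and poly ADP-ribose polymerase 3 (Unigene17645), a DNA damage response enzyme, rose 26.9-fold (14.8 to 54.4). A unigene matched to ubiquitin specific protease 7 (CL2194.Contig1) went from 167 to 2051 counts, 12.1-fold (10.3 to 14.3). A DOMON domain protein (Unigene2990) rose 11.3-fold (8.79 to 14.8) and an SSXT protein (CL3086.Contig1) 10.8-fold (7.96 to 14.9). A unigene with a weak match to a chloride channel (Unigene14561) had 2 and 130 counts, a ratio of 64.1 (17.4 to 535).

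The same ranking of decreases began with a unigene weakly matched to the nuclease HARBI1, of transposon origin (Unigene11870), which fell from 110 to 7 counts, 15.9-fold (7.48 to 40.6). Outside the ranking, a unigene matched to a hypothetical protein (Unigene7616) fell from 198 to 2 counts, a ratio of 0.00995 (0.00120 to 0.0364). A KRAB-A domain protein 2-like unigene (Unigene2264) went from 2732 to 458 counts, 6.05-fold lower (5.48 to 6.70), and histone H1 (Unigene1612), the linker histone of chromatin, fell 3.26-fold (2.89 to 3.68). Nitric oxide synthase (CL2136.Contig2), which makes an antimicrobial and signalling gas, had 30 counts at 0 h and 3 at 24 h, a ratio of 0.0985 (0.0192 to 0.317). A Ras GTPase-activating protein (CL848.Contig1) had 24 and 1 counts, a unigene weakly matched to an acrosin-like protease (Unigene26121) 31 and 4, and a piggyBac element (Unigene21489) 34 and 4. A unigene weakly matched to a lymphoid-specific helicase (CL95.Contig1) had 21 and 0 counts, at least 7.10-fold lower against 3 counts, with an exact upper bound of 0.189 for the ratio. Among the most abundant unigenes, the alpha subunit of the sodium/potassium ATPase (Unigene1187) had a ratio of 1.63, elongation factor 1-alpha (CL2937.Contig1) 1.16 and an unnamed protein (Unigene1117) 0.637.

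Mobile element unigenes, 220 in all, had 22 members up and 14 down, or 26 and 8 with TMM factors, and a median log2 ratio of −0.02, above 98.0% of the random lists, and that median was 0.17 with TMM factors. The members with most counts, 2 endonuclease and reverse transcriptase unigenes (CL361.Contig1 and CL2.Contig3), had ratios of 1.05 and 1.02. Some members passed on few counts, such as Unigene25161 with 13 and 27 and CL860.Contig1 with 38 and 17. Contigs of 1 cluster could go opposite ways, as CL1804.Contig1 with 9 and 67 counts and CL1804.Contig5 with 42 and 23.

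**Figure D3:**
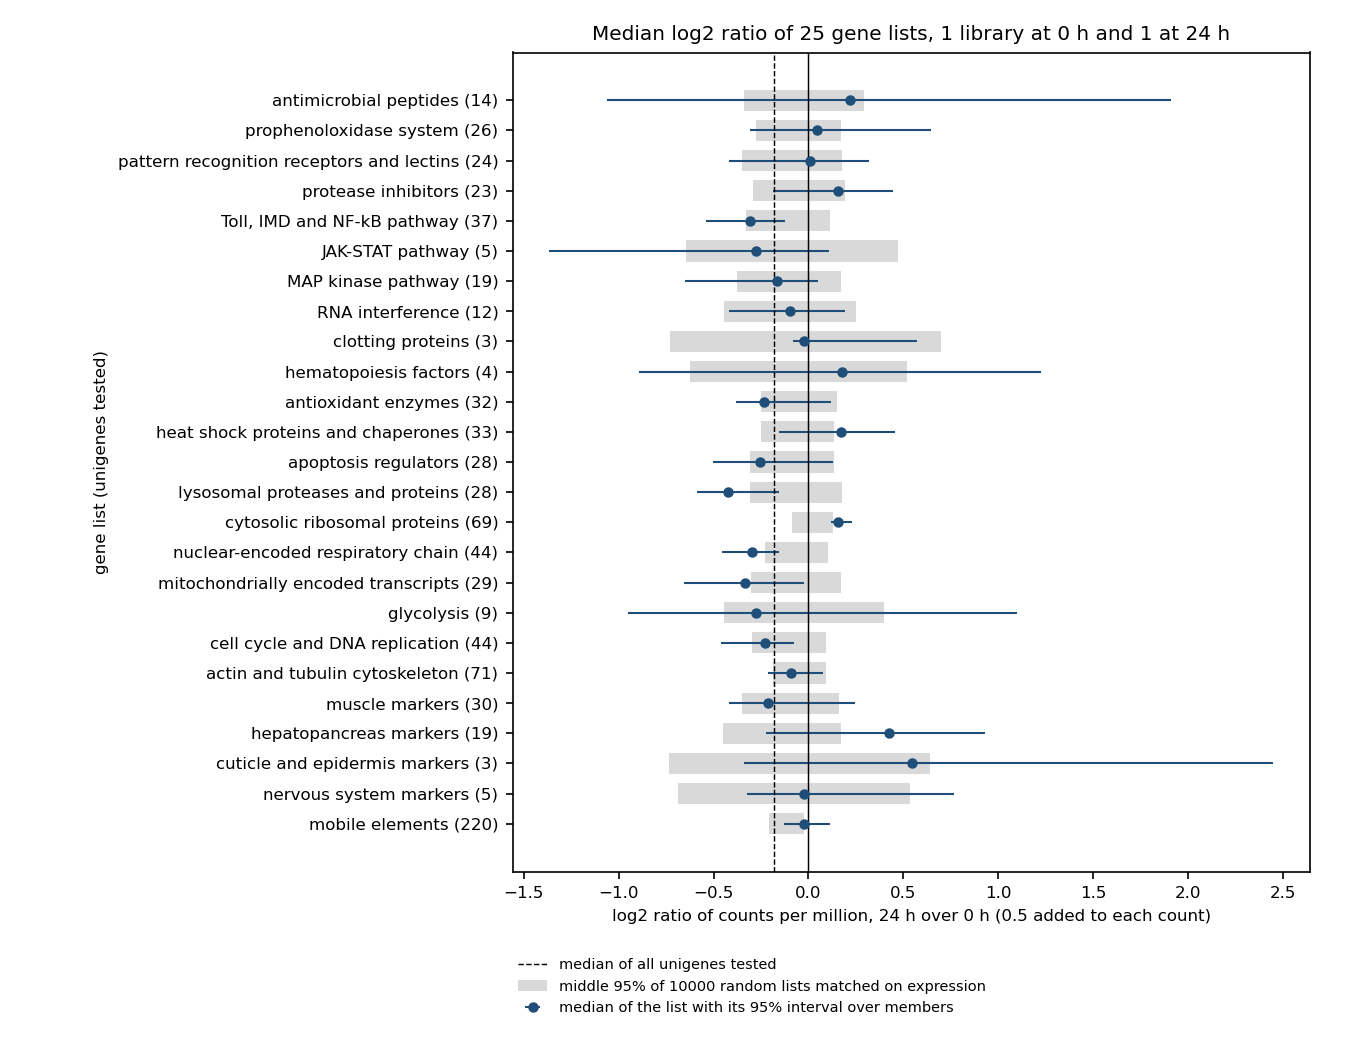
Median log2 ratio (24 h over 0 h) of the 25 gene lists (points) with 95% intervals over members, the middle 95% of 10000 random lists matched on expression (grey bars), 0 (solid line) and the median of all unigenes tested, −0.18 (dashed line). The points of 7 lists lie at or beyond the ends of their grey bars, among them lysosomal proteins at −0.42 and cytosolic ribosomal proteins at 0.16, and the mobile element, cytoskeleton, MAP kinase, RNA interference, clotting and nervous system medians change sign with TMM factors.

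Of 27693 unigenes with enough counts, 1261 were at least 2-fold higher at 24 h and 2455 at least 2-fold lower, so that 66.1% of the passing unigenes were lower. With TMM factors the counts were 1891 higher and 1480 lower, 43.9% lower, and with median of ratios size factors 1657 and 1699, 50.6% lower. The median log2 ratio of all these unigenes was −0.18 with library totals, and TMM factors raised every log2 ratio by 0.19. Relative to that overall median, which unigenes without a protein match pull down, the lists stood at 0.35 for heat shock proteins and chaperones, 0.34 for ribosomal proteins, 0.60 for hepatopancreas markers, −0.24 for lysosomal proteins, −0.12 for the respiratory chain, −0.15 for mitochondrial transcripts and 0.16 for mobile elements. The random lists, drawn from matched unigenes alone, had medians of −0.05, 0.03, −0.13, −0.06, −0.06, −0.06 and −0.11 for these 7. Of the 25 lists, these 7 lay at or beyond the ends of the middle 95% of their random lists, the mobile elements exactly on the end, where 1.25 would by chance. The random lists hold unrelated unigenes, so the 1.25 does not allow for list members that vary together.

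Unigenes without a protein match made up 17034 of those with enough counts, and 740 of them were higher and 1827 lower. Among the 10659 with a match, 521 were higher and 628 lower. In all, 22 unigenes had at least 20 counts at 24 h and 0 at 0 h, and 7 had the opposite. The authors' deposited table gave 1213 unigenes an FDR of at most 0.001 and an absolute log2 ratio of at least 1, of which 538 were higher and 675 lower at 24 h. By the size rule 1192 of those in the authors' deposited table passed too, and the other 21 had a summed count under 20. Of the 3716 unigenes that passed the size rule, 2524 did not pass the FDR of the authors' deposited table.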

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

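The alternatives by protein match and the reduced gene lists were chosen after seeing the data. Only TMM factors turned the balance of higher and lower unigenes: the lower count was 1480 with TMM factors, 43.9% of those that passed, against 66.1% with library totals. Median of ratios size factors brought the balance to near even, at 50.6%. The other settings ranged up to 71.2%, which was the value among unigenes without a protein match. Stricter settings left fewer unigenes by their construction: 377 higher and 496 lower with at least 100 summed counts, 296 and 383 at a ratio of 4, 753 and 1409 at 500 bases or more, 521 and 628 among unigenes with a protein match, and 740 higher among those without. With TMM factors the list medians were −0.11 for Toll, IMD and NF-kB, 0.35 for ribosomal proteins (0.29 with median of ratios), −0.10 for the respiratory chain, −0.0389 for cell cycle and 0.10 for cytoskeleton. The mobile element median turned from −0.02 to 0.17 with TMM factors, 0.11 with median of ratios, 0.0222 without the 10 most abundant unigenes and 0.0603 with counts summed per description. Apart from the summed counts, whose cause was not tested, these shifts are those of the scale itself. The reduced hepatopancreas list had a median of 1.98, as 8 members remained. Unigenes read in 1 library only numbered 106 at 10 counts or more, and 396 unigenes of the authors' deposited table passed at an absolute log2 of 2. Of 214 list medians under alternatives 203 stayed within their intervals, and of 327 values of named unigenes 0 changed direction where the rule had been passed. The scalings could not have turned any, as they raised log2 ratios by 0.19 at most and the rule needs a 2-fold change. Of these named values 111 left their counting interval, which is narrow for abundant unigenes. No paired analysis was possible because each group had 1 library.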

Other observations

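The gene groups, Gene Ontology processes and tests in this part were all chosen after the values were seen. Unigenes named outside those groups in this paragraph and the next were picked among those that passed the size rule. Others of the same names that did not pass are not given. Unigenes named as multidrug resistance-associated or other ABC family proteins had 6 of 24 unigenes up and 1 down, among them multidrug resistance-associated protein 5-like (Unigene7422) at 2.96-fold (2.53 to 3.48) and protein 14 (CL5519.Contig1) from 12 to 53 counts. Of 4 ADP-ribosyl polymerase unigenes 3 rose, with a Parp12a match (Unigene3547) at 2.59-fold beside the polymerase 3 unigene described above, and a zinc finger antiviral protein 1-like unigene (Unigene5022), of a related family, rose 2.51-fold. Transferrin (Unigene6136), which binds iron in hemolymph, rose 8.43-fold (6.90 to 10.4), and an annulin-like transglutaminase (CL4634.Contig1) 8.26-fold (6.48 to 10.7). Single enzymes that rose included folylpolyglutamate synthase (CL654.Contig1) at 8.13-fold, AMP deaminase 2 (Unigene3832) at 2.99-fold, trehalose 6-phosphate synthase (Unigene16027) from 5 to 59 counts and acetyl-coenzyme A synthetase 2-like (Unigene15725) from 14 to 84. Of 2 alcohol dehydrogenase unigenes that passed, CL883.Contig3 rose from 205 to 646 counts and Unigene23756 fell from 42 to 18. An ecto-5-nucleotidase-like unigene (Unigene7048) rose from 15 to 183 counts (ratio interval 7.10 to 21.9). Among serine proteases with no clip domain in their name, 3 of 9 rose and 1 fell, led by Unigene6490 from 55 to 417 counts. The fall (CL1699.Contig2) did not pass with TMM factors, and another contig of its cluster (CL1699.Contig1) had a ratio of 1.64.

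All 9 unigenes of the vacuolar proton pump and its assembly, a complex that acidifies lysosomes and phagosomes, had ratios below 1, with a summed ratio of 0.623 (0.602 to 0.645), although by the size rule 1 of them fell and that one missed it with TMM factors. Of 3 linker histone unigenes 2 fell, the histone H1 described above and an H1 family member 0-like unigene (CL3591.Contig1) at 3.60-fold. The sodium/potassium/chloride cotransporter (Unigene1695) fell 2.55-fold (2.43 to 2.67) and crustacean calcium-binding protein 23 (Unigene7775) from 109 to 28 counts. Gene Ontology processes with at least 15 members numbered 118, and 1 unigene can belong to several of them. By chance 5.9 would lie outside the middle 95% of random lists, a number that varies more when unigenes are shared. The processes that lay outside numbered 11. They included proton transport coupled to ATP hydrolysis (median log2 ratio −0.68, 0 of 16 up and 2 down), engulfment in phagocytosis (−0.37, 1 of 31 up and 1 down), the tricarboxylic acid cycle (−0.38, 0 of 20 up and 2 down, with a summed ratio of 0.981, 0.947 to 1.02), translation (0.13, 0 of 97 up and 2 down), rRNA processing (0.28, 2 of 23 up and 1 down) and cell differentiation (0.36, with 6 of 22 up and 0 down). Mitochondrial proteins of cyst nematodes were the best match of 19 unigenes with weak similarity, which held 1926 counts at 0 h and 1318 at 24 h.

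More unigenes were lower than higher at 24 h with library totals, 66.1% of those that passed. Leaving the 10 most abundant unigenes out of the totals gave 61.4% (59.8 to 63.0, a binomial interval over unigenes), so the larger share of reads in those unigenes cannot account for the whole excess. An assembly from the 0 h reads counted here alone, which would hide transcripts of the 24 h library, is argued against by the 22 unigenes with counts at 24 h only, while a reference that drew mostly on 0 h reads was not tested and stays open. Scaling remains open as a candidate explanation, since TMM factors gave 43.9% and median of ratios size factors 50.6%. Both centre the unigenes by construction, so a scaling effect and a true fall of many low transcripts cannot be told apart without an external standard. A single scaling factor cannot place the excess in unigenes without a protein match, whose median log2 ratio differed by −0.12 from that of matched unigenes in the same bins of expression. The interval of that difference, −0.15 to −0.10, comes from 1000 resamplings of the unigenes and not from replicates. Why the unmatched unigenes were lower, the injection included, was not tested.

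Cryptocyanin, trypsin-like and chymotrypsin unigenes were higher at 24 h. Hepatopancreas tissue in the 24 h sample is a candidate source, as these are transcripts of the digestive gland or of moulting, but preamylase unigenes went the other way, from 33 to 11 summed counts, a ratio of 0.328 (0.150 to 0.666). Other low-count unigenes were split, with a cryptocyanin 2 unigene at 0 and 16 counts and chitinase unigenes at 1 and 9, 9 and 1, and 11 and 2, so the source stays open. A larger share of other tissues in general would raise muscle markers too: the 30 of the list had a summed ratio of 1.24 (1.22 to 1.26), carried by arginine kinase and tropomyosins, while the 27 with fewer than 1000 counts, a limit set after the values were seen, had 0.874 (0.809 to 0.944) and 0.998 (0.924 to 1.08) with TMM factors, which leaves it open. Expression by the hemocytes themselves after injection was not tested.

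The unigene matched to a reverse transcriptase (Unigene16741), of 4862 bases and with a weak match (e-value 7e-09), had 1288 counts at 24 h and 0 at 0 h, and another unigene with an uninformative match (CL763.Contig1) had 1427 and 1. Counting error is excluded by the lower bound of 344 for the ratio of the first. A rise of most mobile elements by 2-fold or more is argued against by the list's median log2 ratio of −0.0211 (−0.129 to 0.113). A smaller rise of the class stays open, as that median lay above 98.0% of the random lists and was 0.17 with TMM factors. In that list 22 members rose and 14 fell, or 26 and 8 with TMM factors, some of them on few counts. The weak match also leaves open whether this unigene is a mobile element. Crabs that differ in the elements they carry or express may account for it, and 7 unigenes read at 0 h only beside 22 at 24 h only do not decide this with 1 library of unknown crab number per group. Induction by the injection or the bacterium stays open for the same reason.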
